A study of Mus musculus with 2 samples.

How the data were processed

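RNA was measured in single cells of 2 libraries of Ly6C+ CD115+ monocytes sorted from the bone marrow of C57BL/6 mice, 1 library from the control group and 1 from the CMML group, grouped by the titles of the samples. The libraries were made with the Chromium Single Cell 3' kit version 3.1 and sequenced with a first read of 28 bp and a second read of 91 bp, per the labels' protocols. The protocol also names a total RNA isolation kit. The values are raw UMI counts per gene and barcode that the authors deposited, with every barcode listed. Cell Ranger 3.0.2 wrote them, per the file headers, on the genome build mm10, per the submitters' processing notes. The gene annotation that was used for counting is not given in the sources used here. No column of the count files was left unused (0 unused).

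Of 31053 gene identifiers, 30934 matched GENCODE M21 (GRCm38/mm10), which supplied 1-based coordinates. Each library listed 6794880 barcodes, of which 677335 in control and 663244 in CMML had at least 1 UMI. A barcode was kept as a cell when its UMIs reached 10% of the 99th percentile of the 3000 barcodes with the most UMIs, which gave a minimum of 6843 UMIs in control and 6533 in CMML, and when it had at least 500 genes and at most 10% mitochondrially encoded UMIs. Scrublet, in scanpy 1.11.5, was run per library at an expected doublet rate of 0.8% per 1000 cells and called 4 control and 14 CMML barcodes, which were left out. Calls that few in libraries of this size mean that the doublet search did not work, so doublets are taken to remain, and an alternative left out the 2% of cells with the highest doublet scores. Retained cells held 95.3% of the control library's UMIs and 95.4% of the CMML library's. Barcodes with 5 to 60 UMIs served as empty droplets: 83842 with 1408454 UMIs in control and 84875 with 1303287 in CMML. Between 500 UMIs and the minimum lay 607 control barcodes with a median mitochondrial share of 0.803% and 59 CMML barcodes with 22.8%.

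Retained cells of both libraries were clustered together without batch correction, on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.6 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, fixed seed). A cluster was named when at least 3 of its 10 leading genes belonged to 1 class of a fixed marker table and no other class had as many. Of 16 clusters, 1 was named dendritic and 1 neutrophil, and their cells were left out of the comparison. An unnamed cluster led by haemoglobin and Ly6C-low genes, with 56 control cells (2.03%) and 92 CMML cells (3.66%), stayed in. Its haemoglobin rank rests on the 1 CMML barcode with 11987 haemoglobin UMIs, since no other retained cell of either library had more than 11. Because most of these clusters held cells of nearly 1 library only, a second clustering was made after the data were examined, on genes under 1.5-fold apart (730 genes with at least 5 CPM were left out), scaled within each library, with 20 principal components, 30 neighbours and resolution 0.6. Cluster shares are taken from it, over 11 clusters, of which 8 had at least 50 compared cells of each library. Equal weights or equal shares of clusters mean that each cluster had the same weight in both libraries, the mean of its share in each. They do not mean that all clusters weighed the same.

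Levels are pooled CPM, the sum of a gene's UMIs over the compared cells as a share of all their UMIs, on the usual CPM scale (total UMIs 62865996 in control and 59768231 in CMML). Intervals are exact at 95%: Poisson for levels, conditional binomial for ratios and Clopper-Pearson for shares of cells. A count of 0 stood at a floor of 3 counts, 0.0477 CPM in control and 0.0502 CPM in CMML. Its fold is given at that floor, and the exact interval can reach a smaller fold. No paired analysis was possible because there was 1 library per group, and no test, p-value or standard error was computed from cells. The numbers of genes at least 2-fold apart describe these 2 libraries and cover genes with at least 20 CPM in 1 of them.

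The lists, the marker table and the rule for named genes were written from general knowledge before the data were examined. The 38 lists were inflammatory cytokines, chemokines, secreted factors linked to cachexia, NF-kB response, immediate early genes, interferon-stimulated genes, MHC class II presentation, MHC class I presentation, alarmins and calcium-binding S100 genes, primary granule genes, secondary and tertiary granule genes, NADPH oxidase and oxidative burst, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, lipid uptake, storage and export, cholesterol synthesis, fatty acid synthesis, unfolded protein and integrated stress response, hypoxia response, iron handling, lysosome and autophagy, complement and Fc receptors, pattern recognition and inflammasome, migration and adhesion, alternative activation and suppression, growth factor receptors and JAK-STAT feedback, RAS-MAPK feedback targets, genes mutated in human CMML, myeloid transcription factors, S phase, G2 and M phase, cytosolic ribosomal proteins, apoptosis and p53 targets, neutrophil-like monocyte genes, dendritic-cell-like monocyte genes and sex-linked genes. Lists share members with each other and with the marker table, so their results are not independent. A list's median covers members with at least 5 CPM in 1 library, and the sex-linked list, with only 2 such members, was given none; medians came with an order-statistic interval and a percentile among 10000 random lists whose genes lay within 100 ranks of each member's mean expression. The rule named the 14 genes with the highest and the 14 with the lowest ratio at 20 CPM or more, without mitochondrially encoded, ribosomal protein, sex-linked, predicted, immunoglobulin, T cell receptor and haemoglobin genes; up to 4 members of each list with the largest difference at 20 CPM or more; and Ly6c2, Csf1r, Ccr2, Itgam, S100a8, S100a9, Il1b, Tnf and Il6.

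Alternatives changed 1 choice at a time: the UMI minimum, the mitochondrial limit, the doublet treatment, the clustering resolution, the cells compared, equal weight per cell, thinning of every cell to 11945 UMIs, the TMM factor of edgeR 4.0.16 in R 4.3.3, totals without mitochondrial and ribosomal protein genes, equal cluster shares and the CPM minimum. Others were chosen after seeing the data: equal shares of the shared clusters, subtraction of the empty-droplet profile at a share estimated from haemoglobin, leaving out the haemoglobin cluster, leaving out the highest doublet scores, and all barcodes with at least 1000 UMIs, in which no cluster was left out, so that the UMI minimum and the cells compared changed together. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

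The comparison was tested on simulated Poisson counts with the pooled means of 5261 genes at 20 CPM or more, in which 200 genes were set 2-fold or 4-fold apart. All 100 genes at 2-fold and all 100 at 4-fold were recovered in the right direction at 1.5-fold or more, and 0 of 5061 unchanged genes reached 1.5-fold. The intervals held the true value for 95.0% of the genes at 2-fold, 97.0% at 4-fold and 95.1% of the unchanged genes. In a second step on the 8715 genes with at least 5 CPM, a list raised 1.5-fold reached percentile 100, and 2 of 36 other lists fell outside the middle 95% of random lists. The simulation had counting error only, so it says nothing about the spread between mice.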

Results

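Single-cell 3' RNA counts were collected from Ly6C-high bone marrow monocytes of C57BL/6 mice, sorted as Ly6C+ CD115+ cells. The control group had 1 library and the CMML group (chronic myelomonocytic leukaemia, taken when weight loss began) had 1 library. The control library held 68317594 UMIs (unique molecular identifiers, 1 per captured RNA molecule) and the CMML library 64632623. After filtering, 2753 control cells with a median of 17191 UMIs and 3719 genes were retained, against 2512 CMML cells with a median of 20358.5 UMIs and 4034 genes. The median mitochondrial share was 3.61% in control cells and 3.70% in CMML cells. Levels are given as CPM, UMI counts pooled over the cells compared and scaled to 1 common library total. Intervals are exact 95% intervals and cover counting error only, since there was 1 library per group. No difference could be tested, because the spread between mice was not measured.

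The comparison asked how the transcriptome of inflammatory monocytes differed between CMML mice at the onset of weight loss and control mice. The CMML cells held far more RNA of the posterior HoxA genes, homeobox regulators of early blood progenitors: Hoxa9 stood at 70.4 CPM against 0.573 in control, a ratio of 123 (88.6 to 176). Of the primary granule genes 8 of 11 were at least 1.5-fold higher and 0 lower, with Elane at 2098 against 959 CPM. Of the monocyte progenitor markers 11 of 13 were at least 1.5-fold higher, with Myb at 89.1 against 25.5. These sets are not independent, since both hold Mpo, Elane, Prtn3, Ctsg and Ms4a3. Among secreted factors linked to cachexia, Lcn2 (lipocalin 2) was 3.18-fold higher (3.08 to 3.28), while Tnf was slightly lower at 6.49 against 7.56 CPM. The median log2 ratio was -0.23 for interferon-stimulated genes, with 7 of 33 members at least 1.5-fold lower and 2 higher, -0.27 for immediate early genes, with 3 of 13 lower and 1 higher, and -0.42 for G2 and M phase genes, with 4 of 26 lower and 0 higher, though 0 were lower with equal weights of the shared clusters. A group of genes present in control cells was at or near 0 in CMML, led by Tceal8 with 1425 control UMIs and 0 CMML UMIs.

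Monocyte identity genes were present in both libraries. Ly6c2, which encodes the sorted Ly6C antigen, was at 2979.8 CPM in CMML and 2005 in control (log2 ratio 0.57). Csf1r, which encodes the sorted CD115, was at 158 against 185 CPM, and Itgam (CD11b) at 105 against 111. Ccr2, the receptor for monocyte exit from marrow, was lower at 748 against 1026 CPM (log2 ratio -0.46). The summed CPM of the 15 Ly6C-high monocyte markers had a ratio of 1.04 (1.04 to 1.05), though their median log2 ratio was -0.26, with 0 of the 15 genes at least 1.5-fold higher and 3 lower, and that of the 13 Ly6C-low markers 0.90 (0.884 to 0.917). Sums of the 13 progenitor markers were 10112 CPM in CMML and 5262 in control, a ratio of 1.92 (1.91 to 1.93), with 11 of the 13 genes at least 1.5-fold higher.

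The cells compared were 2621 control cells, or 95.2% of those retained (94.3 to 96.0), and 2452 CMML cells, or 97.6% (96.9 to 98.2). A dendritic cluster left out of the comparison held 124 control cells (4.50%, 3.76 to 5.35) and 17 CMML cells (0.677%, 0.395 to 1.08). A neutrophil cluster left out held 8 control cells (0.291%, 0.126 to 0.572) and 43 CMML cells (1.71%, 1.24 to 2.30). Among the other marker sums in the compared cells, the ratio was 1.65 (1.63 to 1.68) for neutrophil genes, 1.01 (0.993 to 1.03) for conventional dendritic genes, 1.17 (1.14 to 1.2) for plasmacytoid dendritic genes, 1.16 (1.13 to 1.2) for macrophage genes, 0.819 (0.802 to 0.836) for B cell genes and 1.52 (1.45 to 1.59) for T or NK cell genes. With every retained cell, the clusters named by such markers included, the ratio was 2.55 for neutrophil and 0.631 for conventional dendritic genes. Sums of basophil or mast cell genes had a ratio of 5.60 (5.0 to 6.28). Among them Cpa3 (mast cell carboxypeptidase), chosen after its value was seen, had 652 CMML UMIs and 0 control UMIs. At the floor of 3 counts it was 229-fold higher, or 69.0-fold with equal weights of the shared clusters. Of these clusters 2 of 8 had it at least 1.5-fold higher. Eosinophil genes had a ratio of 0.690 (0.651 to 0.731), platelet genes 1.91 (1.22 to 3.03) and stromal or endothelial genes 1.87 (1.77 to 1.97). The erythroid sum had a ratio of 5.11 (4.93 to 5.30), but 1 CMML barcode held 11987 of the 12300 haemoglobin UMIs of the CMML cells, so Hba-a1 and Hbb-bs are not compared.

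Of 5471 genes with at least 20 CPM in 1 of the libraries, 90 were at least 2-fold higher in CMML and 34 at least 2-fold lower. The median log2 ratio of the 5471 genes was -0.02. Haemoglobin genes, raised by 1 CMML barcode, were not taken out of these numbers. Leaving out the unnamed cluster that holds this barcode gave 85 higher and 37 lower. With each of the 8 shared clusters at the same weight in both libraries (equal weights of the shared clusters), the numbers were 79 and 30. That weight was the cluster's mean share over the libraries, a choice made after the data were examined. By rule, the highest ratios were those of Hoxa10 (1264, 349.6 to 10446, from 2 control UMIs), Ly6k (550.3, 236 to 1696), Hoxa9 and F7, the gene of coagulation factor VII (47.0, 37.5 to 59.7). Hoxa9 (ENSMUSG00000038227) lies on chromosome 6, 52223100 to 52231089, Hoxa10 (ENSMUSG00000000938) on chromosome 6, 52231197 to 52240854 and Hoxa7 (ENSMUSG00000038236) on chromosome 6, 52214491 to 52221854, in GRCm38/mm10 with GENCODE M21 gene models. Hoxa7 had a ratio of 29.4, the Helios gene Ikzf2 29.2, Fam83a 21.5, the class I gene H2-Q6 20.8, and Cd63, a tetraspanin of granule and lysosome membranes, 16.4. Tespa1, Nrg4, Sgip1, Slc4a8 and Nxpe5 completed the 14 highest, with ratios from 11.3 to 13.8. With equal weights of the shared clusters the ratio was 2075 for Hoxa10 and 47.0 for Hoxa7. Outside the rule, and chosen after their values were seen, Hoxa5 had 7.73 against 0.111 CPM, the leukaemia-linked regulators Mecom 5.64 against 0.0318 and Meis1 8.72 against 2.39, and Eya1 19.2 against 0.207. Hoxb4 of the HoxB cluster, also chosen after its value was seen, had a ratio of 1.30 (1.16 to 1.46).

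**Figure D1:**
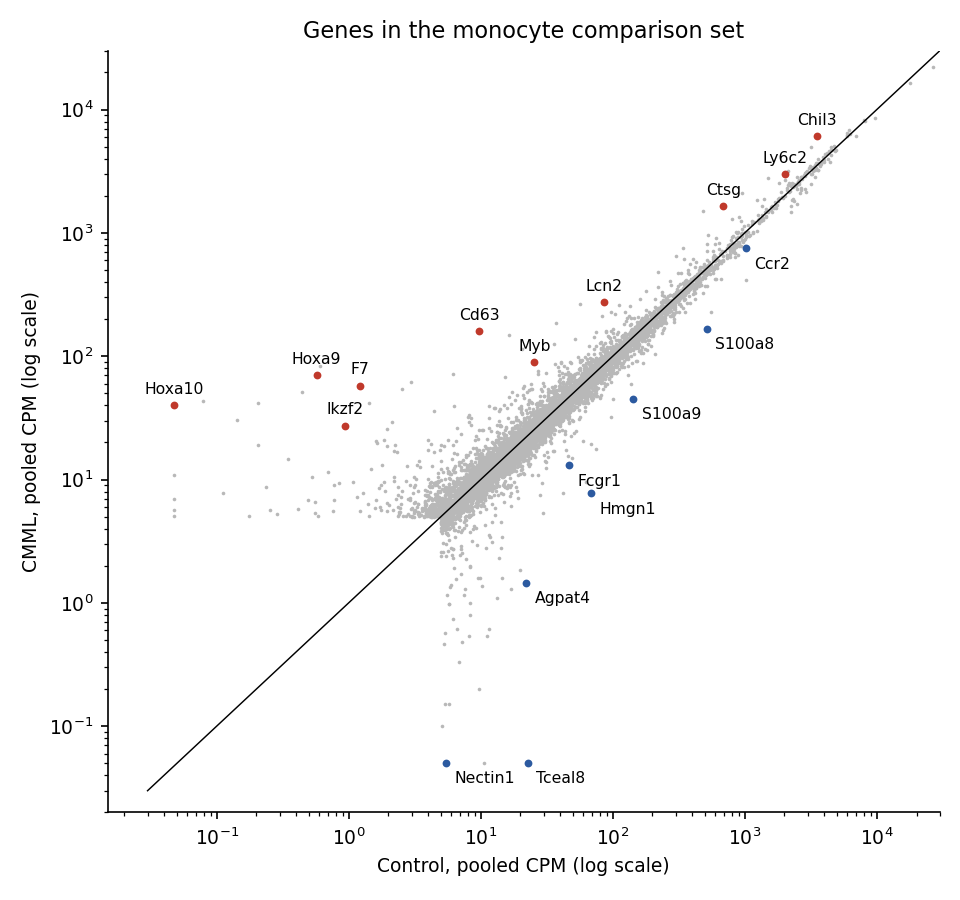
Pooled CPM of genes with at least 5 CPM in 1 library, control on the horizontal and CMML on the vertical axis, both on log scales, with the line of equality and counts under the floor of 3 drawn at that floor. Hoxa9 (0.573 against 70.4 CPM) stands far above the line, and Tceal8 (22.7 against 0 CPM) far below it.

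Tceal8 (ENSMUSG00000051579, chromosome X, 136168984 to 136172342) was at least 452-fold lower in CMML, from 22.7 CPM in control. Next by rule came Agpat4, 15.3-fold lower (12.3 to 19.2), and Hmgn1, a nucleosome-binding protein gene, 8.85-fold lower (8.04 to 9.76). Pla2g7, which encodes an enzyme that inactivates platelet-activating factor, was at 9.59 against 63.0 CPM. Marcks and Ube2e3 were 5.44-fold and 4.18-fold lower. Ptger4, a prostaglandin E2 receptor gene, was at 7.53 against 28.0 CPM, and Fcgr1, the high-affinity IgG receptor gene, at 13.1 against 46.5. Cd24a, Samd9l and Tcf19 had log2 ratios of -1.82, -1.72 and -1.64. S100a8 and S100a9 were also among the 14 lowest and are given with the alarmins. Genes named outside the rule, chosen after their values were seen, included Gspt2 and Nectin1, with 0 CMML UMIs and 10.6 and 5.47 control CPM. At the floor they were 211-fold and 109-fold lower, with exact lower bounds of 171 and 88.2. Akr1e1, chosen in the same way, was 48.2-fold lower (27.4 to 93.9).

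For each of 38 fixed gene lists, members with at least 5 CPM in 1 library were used, members at least 1.5-fold apart were counted as higher or lower, and the median log2 ratio was placed among 10000 random lists of like expression, as a percentile. Random lists drew each gene on its own, so the percentile takes no account of genes that vary together. Primary granule genes had a median of 0.92 (percentile 100), with 8 of 11 members higher and 0 lower. Elane (neutrophil elastase) was 2.19-fold higher (2.17 to 2.21), Ctsg (cathepsin G) 2.39-fold, Prss57 2.59-fold and Srgn, the granule proteoglycan serglycin, 2.23-fold. The neutrophil-like monocyte genes had a median of 0.69 (percentile 100) and 9 of 16 members higher and 2 lower, the lower members being S100a8 and S100a9. Secondary and tertiary granule genes had a median of 0.58 (percentile 100) and 4 of 8 members higher and 0 lower, with Chil3 (Ym1) at 6098 against 3516 CPM and Cd177 at 230.1 against 124. Pglyrp1 of the same list was slightly lower at 50.2 against 63.5 CPM. Intervals held 0 for the medians of primary granule genes (-0.29 to 1.26), neutrophil-like monocyte genes (-0.09 to 1.08) and secondary and tertiary granule genes (-0.34 to 1.67). Myeloid transcription factors had a median of 0.07 (percentile 97.3) and 7 of 21 members higher and 3 lower: Myb was 3.49-fold higher (3.30 to 3.70), Myc 2.69-fold, Tcf4 1.79-fold and Cebpe 1.77-fold, while the monocyte regulator Klf4 was at 189 against 293 CPM. The stem and progenitor genes Kit and Cd34, which are among the progenitor markers, were 4.41-fold and 2.63-fold higher. They were named here after their values were seen.

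**Figure D2:**
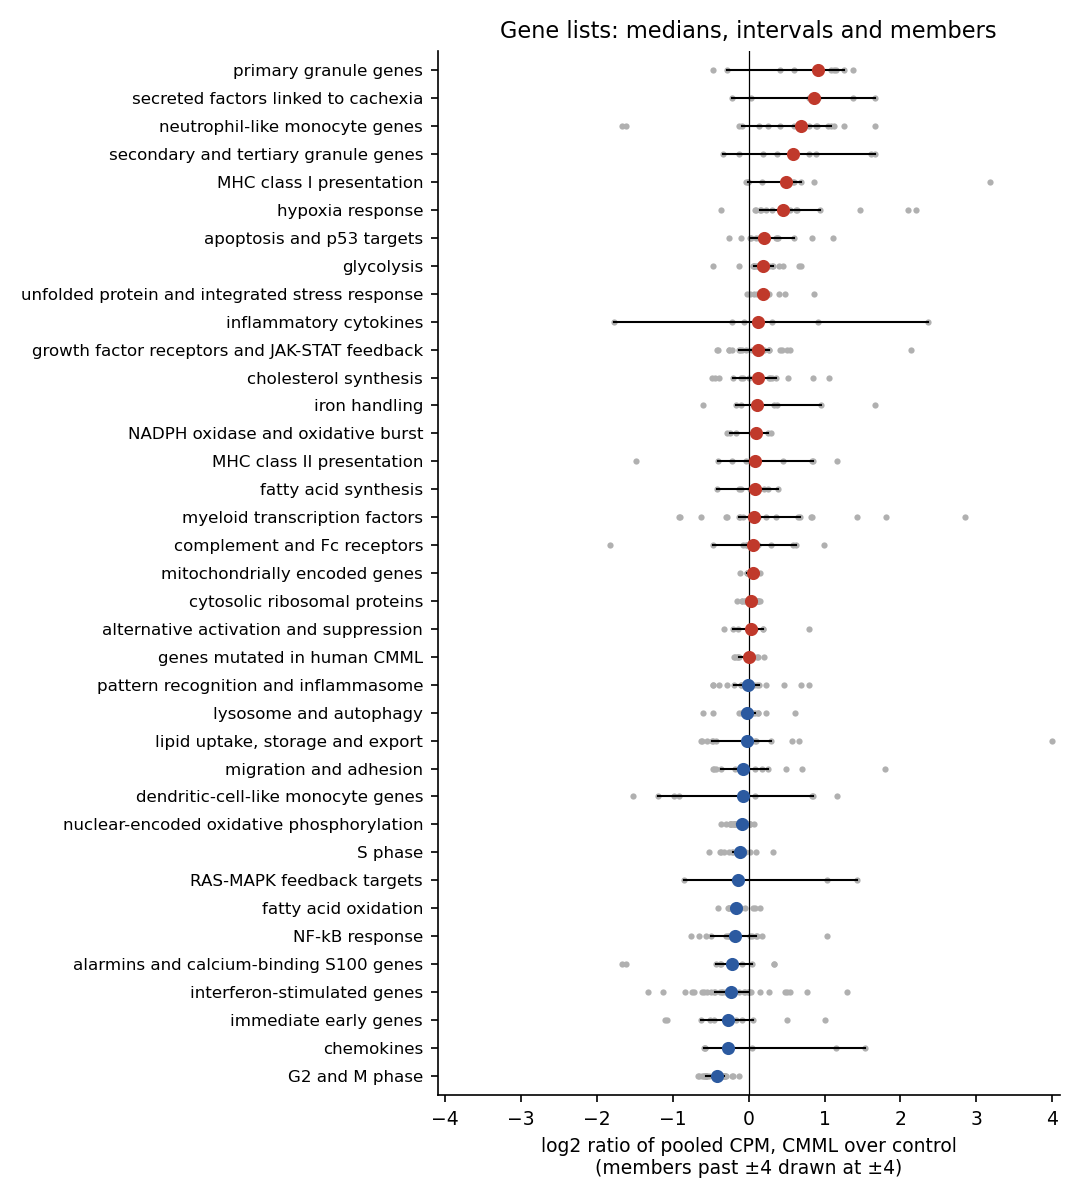
Median log2 ratio of pooled CPM, CMML over control, of 37 gene lists (large points) with the 95% interval of the median from its order statistics (lines) and the members used (small points). Medians run from -0.42 for G2 and M phase to 0.92 for primary granule genes.

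Secreted factors linked to cachexia had a median of 0.86 (percentile 100) and 4 of 6 members higher and 0 lower. The interval of this median, -0.22 to 1.67, held 0. Lcn2 and Chil3 of this list also count among the secondary and tertiary granule genes. Lcn2 was at 274 against 86.2 CPM, Tnfsf12 (TWEAK) at 54.5 against 28.8, and Tgfb1 at 316 against 310.2. Inflammatory cytokines had a median of 0.12 (percentile 81.2) and 2 of 6 members higher and 1 lower. With equal weights of the shared clusters that median was -0.15. Il6 was scarce, with 4 control UMIs and 115 CMML UMIs, a ratio of 30.2 (11.5 to 113). Il1b had a ratio of 1.35 (1.04 to 1.75) and Tnf 0.859 (0.749 to 0.985). Il12a, chosen after its value was seen, was 5.14-fold higher (4.21 to 6.33), as was Angptl4, at 2.60-fold. Chemokines had a median of -0.27 (percentile 4.01) and 2 of 6 members higher and 1 lower, but their mean was positive at 0.16, and the median was 0.13 with equal weights of the shared clusters. Ccl6 was at 326 against 487 CPM, and Ccl9 at 539 against 524.

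NF-kB response genes had a median of -0.18 (percentile 0.435) and 1 of 15 members higher and 2 lower, with Nfkb2 at 13.5 against 22.8 CPM and Tnfaip2 at 94.0 against 83.2. Immediate early genes had a median of -0.27 (percentile 0.05) and 1 of 13 members higher and 3 lower, with Fos at 24.6 against 52.6 CPM and Jun at 17.0 against 35.7. Interferon-stimulated genes had a median of -0.23 (percentile 0) and 2 of 33 members higher and 7 lower. Rtp4 and Ifit3 had log2 ratios of -1.33 and -0.75, while the guanylate-binding protein genes Gbp2 and Gbp3 were higher at 1.29 and 0.77. The interferon median was reversed in sign at a minimum of 100 CPM, and it was 0.30 in shared cluster 5, with 8 of 26 members higher and 0 lower, and 0.37 in cluster 7, with 6 of 19 higher and 0 lower. MHC class I presentation genes had a median of 0.49 (-0.005 to 0.69, percentile 100) and 4 of 13 members higher and 0 lower. They were led by H2-Q7 at 149.7 against 16.5 CPM, H2-K1 at 1305 against 807 and the peptide transporter gene Tap2 at 99.3 against 54.8. MHC class II presentation genes had a median of 0.08 (percentile 90.1) and 3 of 9 members higher and 1 lower. H2-Aa was at 41.2 against 22.9 CPM and H2-Eb1 at 21.4 against 9.54 in the compared cells, and both were lower in CMML when every retained cell was counted, while H2-Eb1 had a ratio of 3.37 with equal weights of the shared clusters. These values depend on the cells left out, since H2-Eb1, H2-Aa and H2-Ab1 lead the dendritic cluster. Dendritic-cell-like monocyte genes had a median of -0.08 (percentile 19.8) and 3 of 9 members higher and 4 lower, with Plbd1 at 105 against 208 CPM. Their median was 0.26 with equal weights of the shared clusters and -0.85 when every retained cell was counted.

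Alarmins and calcium-binding S100 genes had a median of -0.22 (percentile 0.01) and 0 of 12 members higher and 2 lower. With equal weights of the shared clusters the median was -0.06, still with 2 members lower. S100a8 was at 167 against 514 CPM and S100a9 at 45.2 against 144, and both were higher in CMML when every retained cell was counted. The pooled CMML level of S100a9 is not above the 50.4 CPM that free RNA would bring at the share given by haemoglobin. It was uneven, as 24 of 2452 CMML cells held 43.1% of its UMIs, at 2316 CPM, and 26 of 2621 control cells held 82.3%. That share is also rough: control cells of shared cluster 4 held 9.28 CPM of S100a9, under the 42.8 it would bring. In control it rests on 20 haemoglobin UMIs of empty droplets. Empty droplets of the CMML library held 1393 CPM of S100a9 and 1131 of S100a8. S100a4 and Anxa2 had log2 ratios of -0.43 and -0.38. NADPH oxidase and oxidative burst genes had a median of 0.09 (percentile 96.7) and 0 of 11 members higher and 0 lower, with Cybb, the oxidase's catalytic subunit gene, at 691 against 841 CPM. Complement and Fc receptors had a median of 0.05 (percentile 86.1) and 2 of 10 members higher and 1 lower, with Fcgr3 at 409 against 273 CPM and C3 at 229.6 against 319. Pattern recognition and inflammasome genes had a median of -0.01 (percentile 46.4), a mean of 0.02 and 2 of 18 members higher and 0 lower, with Cd14 at 23.8 against 14.8 CPM and Tlr2 at 37.0 against 48.6. Migration and adhesion genes had a median of -0.07 (percentile 18.9), a mean of 0.08 and 2 of 15 members higher and 0 lower, with the adhesion gene Pecam1 (CD31) 3.46-fold higher and Cx3cr1 at 84.0 against 116 CPM. Alternative activation and suppression genes had a median of 0.03 (percentile 70.4) and 1 of 9 members higher and 0 lower, with Vsir (VISTA) at 172 against 216 CPM. With equal weights of the shared clusters the medians of pattern recognition and of migration were 0.07 and 0.02.

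In metabolism, glycolysis genes had a median of 0.19 (percentile 99.97) and 2 of 17 members higher and 0 lower, with Hk3 1.58-fold higher and Gapdh at 2661 against 2021 CPM. Nuclear-encoded oxidative phosphorylation had a median of -0.09 (percentile 5.63) and 0 of 37 members higher and 0 lower, with Sdha at a log2 ratio of -0.37. Mitochondrially encoded genes had a median of 0.05 (percentile 84.1) and 0 of 13 members higher and 0 lower, from -0.11 for mt-Nd4l to 0.15 for mt-Nd3. Fatty acid oxidation had a median of -0.17 (percentile 0.360) and 0 of 17 members higher and 0 lower, with Etfa at -0.40 and Cpt1a, the carnitine shuttle gene, at -0.26. Fatty acid synthesis had a median of 0.08 (percentile 83.5) and 0 of 8 members higher and 0 lower, with Acly at 0.02. For lipid uptake, storage and export the median was -0.02 (percentile 51.2) and the mean 0.24, with 2 of 16 members higher and 2 lower: Lpl (lipoprotein lipase) was 1.59-fold higher, Lrp1 had a log2 ratio of -0.62 and Fabp5 -0.61. Cholesterol synthesis had a median of 0.12 (percentile 96.8) and 2 of 16 members higher and 0 lower, with Sc5d 2.09-fold and Fdps 1.79-fold higher. Iron handling had a median of 0.11 (percentile 96.1) and 2 of 9 members higher and 1 lower, with the ferritin receptor gene Ncoa4 1.94-fold higher. Lysosome and autophagy genes had a median of -0.02 (percentile 60.5) and 1 of 18 members higher and 1 lower, with Psap at 1480.3 against 2249 CPM. With equal weights of the shared clusters the medians of lysosome and of lipid uptake were 0.06 and 0.02.

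Hypoxia response genes had a median of 0.45 (percentile 100) and 6 of 16 members higher and 0 lower, with Hif1a at 43.6 against 28.0 CPM, Mif at 331 against 237 and, chosen after its value was seen, Egln3 at 12.8 against 2.78. The unfolded protein and integrated stress response had a median of 0.19 (percentile 100) and 1 of 18 members higher and 0 lower, with the chaperone gene Calr 1.82-fold higher (1.80 to 1.85). Apoptosis and p53 targets had a median of 0.20 (percentile 99.8) and 3 of 14 members higher and 0 lower, with Bcl2 2.16-fold and Cdkn1a 1.30-fold higher. Weighting by the 2 clusters of the main clustering with enough cells of both libraries reversed this median and those of the interferon-stimulated genes and ribosomal proteins, and reversed Bcl2, Fos, Gfi1 and Angptl4. Growth factor receptors and JAK-STAT feedback had a median of 0.12 (percentile 99.4) and 1 of 21 members higher and 0 lower, with Pim1 at 0.55, Il3ra at 0.41 and Il6st at -0.41. RAS-MAPK feedback targets had a median of -0.14 (percentile 16.9), a mean of 0.25 and 2 of 5 members higher and 1 lower, with Dusp6, an ERK phosphatase gene, at 12.9 against 23.3 CPM. Genes mutated in human CMML had a median of 0.01 (percentile 69.1), a mean of -0.01 and 0 of 17 members higher and 0 lower, with Ptpn11 at 0.21.

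G2 and M phase genes had a median of -0.42 (percentile 0) and 0 of 26 members higher and 4 lower, with Plk1 at 38.7 against 61.7 CPM and Ube2c at 229.9 against 352. Given equal weights of the shared clusters, their median was -0.15 and 0 of 26 members were lower, while single clusters ranged from 0.02 in cluster 4 to -0.63 in cluster 6, with 15 of 26 lower, and -0.78 in cluster 7, with 17 of 26 lower. S phase genes had a median of -0.11 (percentile 1.21) and 0 of 24 members higher and 0 lower, with Rrm2 at -0.53, and their sign was reversed when each cell had equal weight. Cytosolic ribosomal proteins had a median of 0.04 (percentile 70.9) and 0 of 25 members higher and 0 lower, from -0.15 for Rps12 to 0.15 for Rpl5, and -0.05 with equal weights of the shared clusters. Of the sex-linked genes, 2 had enough counts, too few for a median, and 0 were higher or lower by 1.5-fold: Xist was at 708 CPM in CMML and 577 in control, while Ddx3y and Eif2s3y of the Y chromosome had 0 UMIs in both libraries.

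Cluster sizes were compared in a clustering built without the genes that differed between the libraries, which gave 11 shared clusters. Cluster 7, led by Mpo and Ms4a3 with progenitor genes, held 5.92% of control cells (5.07 to 6.87) and 7.32% of CMML cells (6.34 to 8.41). Cluster 9, led by Ccnb1 and Ube2c of mitosis, held 4.61% (3.86 to 5.46) and 2.83% (2.21 to 3.55), and cluster 5, led by Ccne2 and Ccne1 of S phase, 9.44% (8.38 to 10.6) and 6.81% (5.85 to 7.86). Cluster 4, led by Ace and H2-Aa beside haemoglobin genes of the 1 rich CMML barcode, held 12.9% (11.6 to 14.2) and 7.44% (6.45 to 8.54). The interferon cluster 10, led by Cxcl10 and Ifit3, held 1.63% (1.19 to 2.18) and 1.43% (1.01 to 1.98). Cluster 8 held 8 control cells and 292 CMML cells (0.291%, 0.126 to 0.572, against 11.6%, 10.4 to 12.9). Of the fixed markers it had 12 neutrophil, 9 progenitor and 8 T or NK cell genes raised, with Ltf and Trbc2 among its leading genes. Its genes were ranked with equal weight of both libraries, so the 8 control cells counted as much as the 292 CMML cells. Its CMML cells are therefore not read as neutrophils. Their progenitor marker sum was high, at 19473 CPM, against 24949.5 in the CMML cells of cluster 7 and 1622 in those of cluster 1. Of the cells of cluster 8, 2 control and 256 CMML cells (10.4% of the CMML cells compared) stay in the pooled values. Equal weights of the shared clusters leave them out. Clusters 1, 2, 3 and 6 held 19.2%, 24.1%, 13.4% and 6.36% of control cells and 23.7%, 16.8%, 12.1% and 9.47% of CMML cells. The dendritic cluster 11 held 2.14% (1.64 to 2.76) and 0.518% (0.276 to 0.883). This clustering left out genes that differed, so these shares may not give the whole difference in progenitor-like cells. In the main clustering, clusters 8, 9 and 14 held 242, 233 and 110 CMML cells and 2, 3 and 3 control cells. Their progenitor marker sums were 19863, 23576 and 22232 CPM. Cluster 11 of the main clustering, at 20838 CPM, held 183 control and 12 CMML cells.

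**Figure D3:**
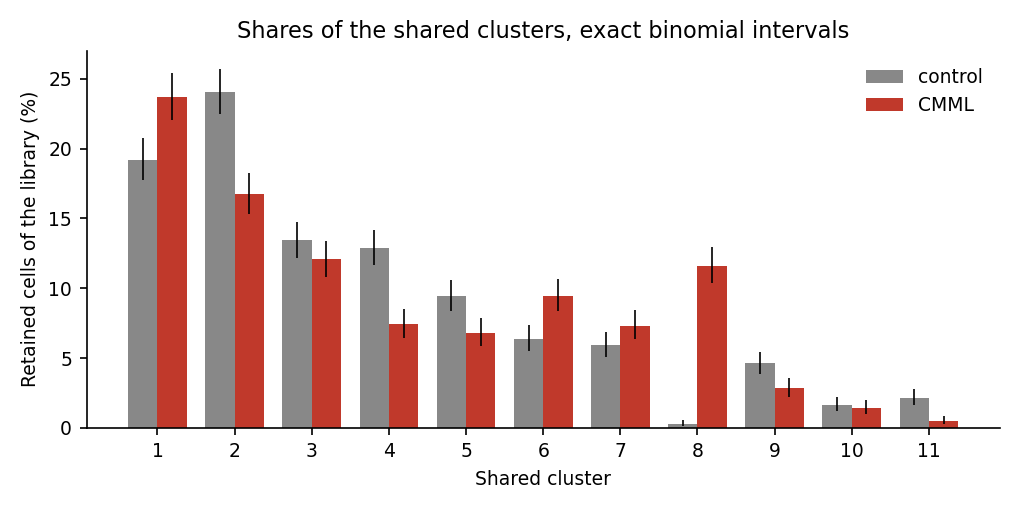
Share of each library's retained cells in the 11 shared clusters, in percent, with exact 95% binomial intervals as error bars. Cluster 8 held 0.291% of control cells and 11.6% of CMML cells.

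Within the 8 shared clusters with at least 50 compared cells of each library, Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa9 and Hoxa10, summed, were higher in CMML in every cluster. The ratio was smallest in the progenitor cluster 7, at 171.5 against 11.8 CPM (ratio 14.6, 11.9 to 18.0). In cluster 3, led by histone genes, the sums were 246.8 and 0.955 CPM. Lcn2, Elane and Myb were at least 1.5-fold higher in 8, 7 and 8 of these 8 clusters, and Chil3 in 8. For Lcn2 this depends on the cells left out. With every retained cell its log2 ratio fell from 1.89 to 0.44 in cluster 6, under 1.5-fold, and from 1.24 to 0.64 in cluster 7. Pla2g7, Hmgn1 and Fcgr1 were at least 1.5-fold lower in 8 of 8. The clusters do not match the libraries in progenitor state, so these counts do not separate it from other differences. Progenitor marker sums over retained cells were 3554 CPM in control and 10529 in CMML in cluster 3. They were 1990 and 5367 in cluster 9, but 21874 and 24949.5 in cluster 7.

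**Figure D4:**
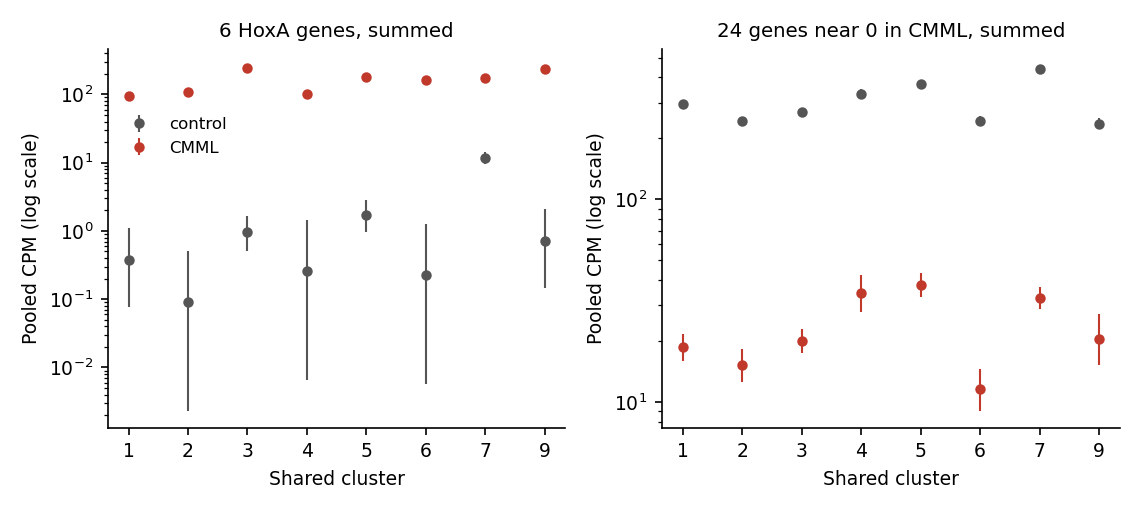
Pooled CPM on a log scale by shared cluster for 6 summed HoxA genes (left) and 24 summed genes near 0 in CMML (right), control and CMML, with exact 95% Poisson intervals as error bars. In cluster 7 the HoxA sums were 11.8 CPM in control and 171.5 CPM in CMML.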

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

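All tests in this part were chosen after the results were seen, and differences between mice were not tested, as there was 1 library per group.

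The first pattern was the higher level of 6 HoxA genes in CMML. A change in the shares of the shared clusters was argued against. The ratio of the summed counts was 14.6 (11.9 to 18.0) in cluster 7, where it was smallest. Among these clusters the highest control level was 11.8 CPM and the lowest CMML level 95.2. A shift of cell state within clusters cannot be excluded, since they do not match progenitor state. Progenitor marker sums over retained cells were 3554 CPM in control and 10529 in CMML in cluster 3, though closer in cluster 7, at 21874 and 24949.5. Free RNA was argued against as the source in cells, because the cells held 0.716 (0.638 to 0.806) of the level in empty droplets. Haemoglobin, without the 1 rich barcode, held 0.0362 (0.0301 to 0.0437). Immunoglobulin, also planned as a measure of free RNA, stood at 76.4% in CMML cells, so by it alone free RNA would not be argued against. But S100a9 stood at only 0.0325 (0.0306 to 0.0345), which limits the share of free RNA if empty droplets give its make-up. A mislabelled sample and a difference between library batches were not tested, since each group had 1 library. A biological difference between CMML and control cells stays open as an untested hypothesis.

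The second pattern was a set of 24 genes with at least 5 CPM in control and at least 8-fold lower in CMML, among them Tceal8, Gspt2, Nectin1, Hnmt and Adam19. A change in the shares of the shared clusters was argued against, since the ratio of their summed counts was 0.104 (0.0831 to 0.129) in the cluster where it was largest. Among these clusters the lowest control level was 236 CPM and the highest CMML level 38.0. A shift of cell state within clusters cannot be excluded here either. A single linked chromosome segment carried along from another strain was argued against, since at most 2 of the 24 genes lay within 10 Mb and the genes lay on 15 chromosomes. Strain variants at several places, which could keep reads from being counted, were not tested, as no reads were analysed here. A biological difference between the groups stays open as well and was not tested.

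The third pattern was the lower S100a8 and S100a9 in the compared CMML cells. The direction depends on the cells compared: with the neutrophil cluster, which these genes help to lead, and the dendritic cluster back, the log2 ratios were 1.09 and 1.64, so what follows holds for the compared cells only. For S100a8, a few rich cells were argued against as the whole cause, since without the richest 1% of cells of each library the log2 ratio was -1.81 (-1.86 to -1.76). For S100a9 the same step gave 0.010 (-0.09 to 0.11), with 25.8 CPM left in control and 25.9 in CMML. Its pooled difference therefore lay in the richest 1% of cells, where 26 of 2621 control cells held 82.3% of its UMIs and 24 of 2452 CMML cells 43.1%. Whether the other cells differed cannot be told, since the levels left lay under the 42.8 and 50.4 CPM that free RNA would bring at the haemoglobin share. RNA of cells like the control library's neutrophil cluster, of 8 cells, was examined as the source of S100a8 in the 26 richest control cells. Their Camp per S100a8 UMI was 0.00111 (0.000407 to 0.00242) of that in the cluster. This cannot decide the question, since the cluster, led by Camp, had been left out before the 26 cells were picked. By the same measure Ltf and Retnlg were at 0, but Ngp was at 0.103 (0.0922 to 0.114), Wfdc21 at 0.391, Lcn2 at 0.794, Cd177 at 1.35, Mmp8 at 1.56 and Fcnb at 3.62. Neutrophil cells, of that or another stage, stay open, untested, as do the kind of these rich cells and a difference between the groups.

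H2-Aa stood out because its directions differed among shared clusters, a difference that was not tested: its log2 ratio was 1.33 in cluster 6 and -1.13 in cluster 3. These directions hold at 1.5-fold or more after the free RNA share given by haemoglobin is taken off, and with every retained cell they were 1.31 and -1.11. The 2.01 of H2-Aa in cluster 4 is not read, since it was 0.10 with every retained cell. For S100a8 and S100a9 in cluster 4 no direction is read, since 27.6 and 35.4 CPM in CMML lay under the 40.9 and 50.4 CPM that free RNA would bring there.

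The empty droplets, which the comparison of cells left out, stood out for some genes with a higher level in the CMML library than in control. Haemoglobin genes stood at 141.9 CPM (122 to 164) against 14.2 (8.67 to 21.9). S100a9 stood at 1393 CPM against 435, Ngp at 501 against 126 and Camp at 436 against 138. Immunoglobulin genes went the other way, at 361 against 474.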

How the results depend on the processing

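Of 19 alternatives, some were chosen after seeing the data: equal shares of the shared clusters, empty-droplet subtraction by haemoglobin, leaving out the haemoglobin cluster or the highest doublet scores, and all barcodes with at least 1000 UMIs. A value counts as reversed when it changed sign although its interval lay on 1 side of 0, and, for a gene, it was at least 1.5-fold apart; otherwise it counts as moved when it left its interval. By this rule, of 3667 values of 193 named genes, 2972 stayed within their counting interval, 674 moved and 21 reversed. Changes of the CPM minimum and the minimum of 1000 UMIs for clustered cells left gene ratios unchanged by construction. They add to the number that stayed. Of 696 list medians 15 moved and 7 reversed. Any change of sign was more frequent: 52 gene values and 46 medians, in 17 lists, most often pattern recognition and inflammasome (7 alternatives), chemokines and MHC class II presentation (5 each). The numbers of cells kept stayed within 1.5 times the first choice, from 2063 to 2877 in control and from 2106 to 2532 in CMML. Unless said otherwise, the cause was not tested.

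The share of cells compared moved with the clustering resolution, since clusters named by their leading genes differ: 97.5% of control cells at resolution 0.3, and 85.9% of control and 95.7% of CMML cells at 1.2. At resolution 0.3 the median of MHC class II presentation moved to -0.56, and H2-Eb1, H2-Aa and H2-Ab1 reversed to log2 ratios of -0.56, -0.62 and -0.61. With all retained cells, which brings back the dendritic and neutrophil clusters, that median was -0.45, the same 3 genes were at -0.44, -0.57 and -0.60, S100a9 at 1.64 and S100a8 at 1.09. With all barcodes with at least 1000 UMIs, which changed the UMI minimum and also left no cluster out, the median was -0.45, H2-Eb1, H2-Aa and H2-Ab1 were at -0.44, -0.57 and -0.60, S100a9 at 1.64 and S100a8 at 1.10.

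With equal weight per cell the median of genes mutated in human CMML was 0.045 and that of S phase reversed to 0.015. Cells thinned to one depth gave 0.056 for S phase. Equal shares of the shared clusters gave -0.026 for S phase, -0.15 for G2 and M phase and -0.049, reversed, for cytosolic ribosomal proteins. Medians whose interval held 0 also changed sign there: chemokines 0.13, inflammatory cytokines -0.15, dendritic-cell-like monocyte genes 0.26, pattern recognition and inflammasome 0.073, lysosome and autophagy 0.060, migration and adhesion 0.018 and lipid uptake, storage and export 0.019.

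Equal cluster shares over clusters of the main clustering rested on 2 clusters with at least 50 cells of each library, so they describe few of the CMML cells. There 54 genes were at least 2-fold lower. Medians were 0.21 for alarmins and calcium-binding S100 genes, 0.32 for glycolysis, -0.25 for fatty acid oxidation, 0.12 for the unfolded protein and integrated stress response, 0.15 for lysosome and autophagy, 0.17 for pattern recognition and inflammasome, 0.21 for alternative activation and suppression, -0.28 for S phase and -0.051 for G2 and M phase. Reversed medians were 0.087 for interferon-stimulated genes, -0.19 for cytosolic ribosomal proteins and -0.12 for apoptosis and p53 targets. Reversed genes were S100a9 (1.64), Fos (0.048), H2-Eb1 (-0.58), H2-Aa (-0.38), H2-Ab1 (-0.52), Bcl2 (-0.36), Gfi1 (-3.56) and Angptl4 (-1.13).

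With no minimum CPM, 954 genes were at least 2-fold higher and 705 lower, since scarce genes entered. A minimum of 100 CPM left 19 higher and 6 lower, since fewer genes were counted, and reversed the median of interferon-stimulated genes to 0.013. Under every alternative but these 2 and the equal shares of the main clustering, from 79 to 98 genes were at least 2-fold higher and from 30 to 37 lower. TMM scaling and totals without mitochondrial and ribosomal protein genes moved the median of all genes by less than 0.1 on the log2 scale.

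The minimum of 1000 UMIs for clustered cells moved nothing by construction, as clustered cells had more. Subtraction of free RNA estimated from haemoglobin and immunoglobulin was not run, because immunoglobulin in cells stood at 73.4% of its level in empty droplets in control and 76.4% in CMML, which would have given shares of 71.5% and 55.9%. Haemoglobin alone gave 9.86% and 3.62%. Depth limited genes such as Il6 with 4 control UMIs, whose ratios have wide intervals.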

Other observations

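The tests in this part were chosen after the results were seen.

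Genes at least 4-fold higher in CMML at 20 CPM or more, without haemoglobin, numbered 23, and 7 of them had another such gene within 100 kb: H2-Q6 with H2-Q7, Sgip1 with Tctex1d1, and Hoxa7, Hoxa9 and Hoxa10. None of 10000 random draws of as many genes had more than 6. The hypothesis that neighbouring genes are higher together was prompted by these genes, and 5 of the 7 are related neighbours, of the HoxA and H2-Q families. With each family counted once, 2 genes had such a neighbour (percentile 96.5), inside the middle 95% of random draws, so the hypothesis stays open.

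Of the 24 genes near 0 in CMML, 4 were X-linked, where 10000 random draws from 8164 genes with at least 5 CPM in control had a median of 1 (percentile 99.7). A hypothesis is that X-linked genes are over-represented among them, but it was prompted by these genes, and Rtl8a and Rtl8b are related neighbours. With these counted once, 3 were X-linked (percentile 98.5).

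The hypothesis that cells with the control profile made up part of the CMML library was tested on Tceal8, Gspt2 and Nectin1, which had 2436 control UMIs and 0 CMML UMIs together. Their count of 0 gives a limit of 0.130% of the RNA of the compared CMML cells, but the genes were chosen for that count, so the test decides nothing and the hypothesis stays open.

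In the CMML library, S100a9 in cells stood at 0.0325 (0.0306 to 0.0345) of its level in empty droplets, and S100a8 at 0.148 (0.140 to 0.156). Haemoglobin stood at 0.0362 (0.0301 to 0.0437), an interval that holds the whole interval of S100a9. The control cells richest in S100a8, 26 in number, held 20877 CPM of S100a8, 2719 CPM of Elane, 7.34 CPM of Camp, 438 CPM of Ngp and 1115 CPM of Lcn2, where all compared control cells held 8.21 CPM of Ngp and 86.2 of Lcn2.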
